A study of Cryptomeria japonica with 48 samples.

How the data were processed

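The series holds 48 single-colour microarrays of total RNA from lateral branch apexes of Japanese cedar (Cryptomeria japonica), a conifer that sheds pollen from male strobili. Material of 3 selected forest trees, called plus-trees and named 1503, 0840 and 1725, had been multiplied by grafting. GA3, a gibberellin hormone, was given to branches of the treated individuals to induce male strobili, and untreated individuals served as control. Each plus-tree gave 1 array per treatment at each of 8 times, namely 1 day before treatment and 3 hours, 1 day, 3 days, 1 week, 2 weeks, 4 weeks and 6 weeks after it, so that the 16 groups of treatment and time have 3 arrays each. The series text also names 0 hours, a label that none of the 48 arrays carries.

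Each deposited scanner file comes from Agilent Feature Extraction 11.5.1.1 and describes 62976 spots of a custom array, of which 61657 belong to 19304 probes and 1319 are control spots. The values used are, per the file headers, the processed intensity of each spot in arbitrary units, which the scanner program had corrected for background and spatial trend and which the authors had not normalised between arrays. The raw median intensity of the spot and of its local background, also per the file headers, served 1 alternative. Flags of other kinds in the deposited files, each 0 or 1 per spot, gave whether a spot was well above background and whether it was an outlier. The deposited value table was checked against the scanner files over 62976 spots per array and equals the processed intensity, with a largest relative difference of 0.

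Intensities were taken to log2, the 75th percentile of the noncontrol spots of the same array was subtracted, and the 3 spots (15559 probes) or 4 spots (3745 probes) of a probe were averaged without spots marked as outliers, which left 258 missing values. A probe was counted as above background on an array when a share of its spots over 0.5 was marked so. Tested were the 15327 probes above background on all 3 arrays of at least 1 group, of which 12523 were so on all 48 arrays. A fold change against a group with no array above background is given as a bound, with the lowest value among probes above background on the same array in place of lower values. Such a bound does not exist for a change since the day before treatment of an isotig whose baseline arrays in control were not above background, and these changes are called fitted. Array depth has no count, and the number of arrays limits the precision. Pearson correlations between arrays of a group lay between 0.847 and 0.954.

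The arrays sit on 6 slides of 8 arrays, each slide holding the 8 times of 1 tree under 1 treatment. Each time has the same place on every slide, so time and place are confounded. The GA3 slides of trees 1503 and 0840 were scanned in an earlier month than the other 4 slides. Linear models were fitted with limma 3.58.1 in R 4.3.3, with the package data.table (version 1.17.8) for reading. The model for GA3 against control had 1 mean for each of the 16 groups and 32 residual degrees of freedom, with no block, since the series text names none. Beside it stands a model with tree as a block (30 degrees of freedom). The change since 1 day before treatment, GA3 minus control, was tested in a model with slide as a block (28 degrees of freedom), where a constant offset of a slide or individual cancels. Moderated F tests covered any time after treatment, the course in control, the course in GA3 and the 3 trees. P values are two-sided with Benjamini-Hochberg adjustment over the probes tested, and a probe is called at an adjusted p under 0.05. As a check that arrays of the same tree are paired, deviations of a control array from its group mean were correlated with those of the GA3 array of the same tree and time. The correlation was above 0.1 in 24 of 24 pairs, with a median of 0.501, so blocked values are given beside the unblocked ones. It was at most 0.005 with the GA3 arrays of the other trees, which is no separate evidence, as the deviations of a group cancel over its trees.

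The groups, tests, thresholds and most alternatives were chosen before the data were examined, as were the rule for naming and the lists of genes. The probes stand for assembled transcripts (isotigs) named reCj with a number, and 0 of the 19304 names occur in the reference table of 61123 genes. The gene lists were therefore not tested, and no function is given for any isotig. The naming rule then allows at most 2 isotigs that rose and 2 that fell per comparison, those with the largest log2 fold change among called isotigs with the same sign in all 3 trees. Each isotig name also carries a code of 4 places that hold the letters M, S, W and R or a dash, a code that the files do not define. The 16 combinations were tested as groups with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with limma's fry, a choice made after the names were read. Code groups were compared with the other probes by two-sided Fisher's exact tests on the calls. For these set tests 114 missing values were set to the group mean.

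The alternatives were quantile normalisation, normexp background correction (offset 50), no filter, a filter on every array, outlier spots kept, a trended and robust variance, an absolute log2 fold change of at least 1, tree or slide as a block, the 6 arrays of a time alone, and leaving out each tree or each array of a time. Added after seeing the data were scan month as a block, a covariate for the leading axis of variation within groups, and leaving out arrays with a 75th percentile under 600. The axis is the first singular vector of the residuals after group and tree. Arrays were scored on it with their full centred values, so a difference between treatments along the axis enters the score. On simulated data with 200 changed probes, the model without a block recovered 38.0% of changes of 1 and 69.0% of changes of 2 on the log2 scale at 6 weeks with 2 false calls, the tree block 37.0% and 69.0% with 4 false calls, and the change model with slide block 13.0% and 39.0% with 2 false calls. A simulated shift of 0.5 in 1 code group was the single group that camera called. The simulated noise was independent between probes and arrays, without effects of tree, slide or axis. The false calls and the camera check therefore do not measure error rates on the real arrays. The recovered shares do not rank the models there either, as the simulation held no tree or slide variation for a block to remove. Python 3.11.15 drew the figures.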

Results

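Expression in lateral branch apexes was measured on 48 arrays, 3 per group, to follow the induction of male strobili by GA3. Array signal, the 75th percentile of the processed intensity, lay between 697 and 1477 arbitrary units on the 24 GA3 arrays and between 376 and 1193 on the 24 control arrays. A signal under 600 occurred on 7 control arrays and 0 GA3 arrays, and the 3 control arrays 1 day after treatment lay between 408 and 526. The leading axis of variation within groups held 34.2% of that variation, with a mean score of 0.21 ± 0.12 (SD) on the GA3 arrays and -0.21 ± 0.37 on the control arrays. Across the 48 arrays, which are not independent within a slide, the score and the log2 signal had a Pearson r of 0.619 (permutation p = 3e-05, adjusted 0.00012) and a Spearman rho of 0.63 (permutation p = 2e-05). Pearson r was 0.385 within GA3 (permutation p = 0.0634, adjusted 0.0634; rho 0.386) and 0.457 within control (permutation p = 0.0254, adjusted 0.0339; rho 0.51), and 0.515 without the 2 arrays of most extreme signal, these 4 values forming 1 family.

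**Figure D1:**
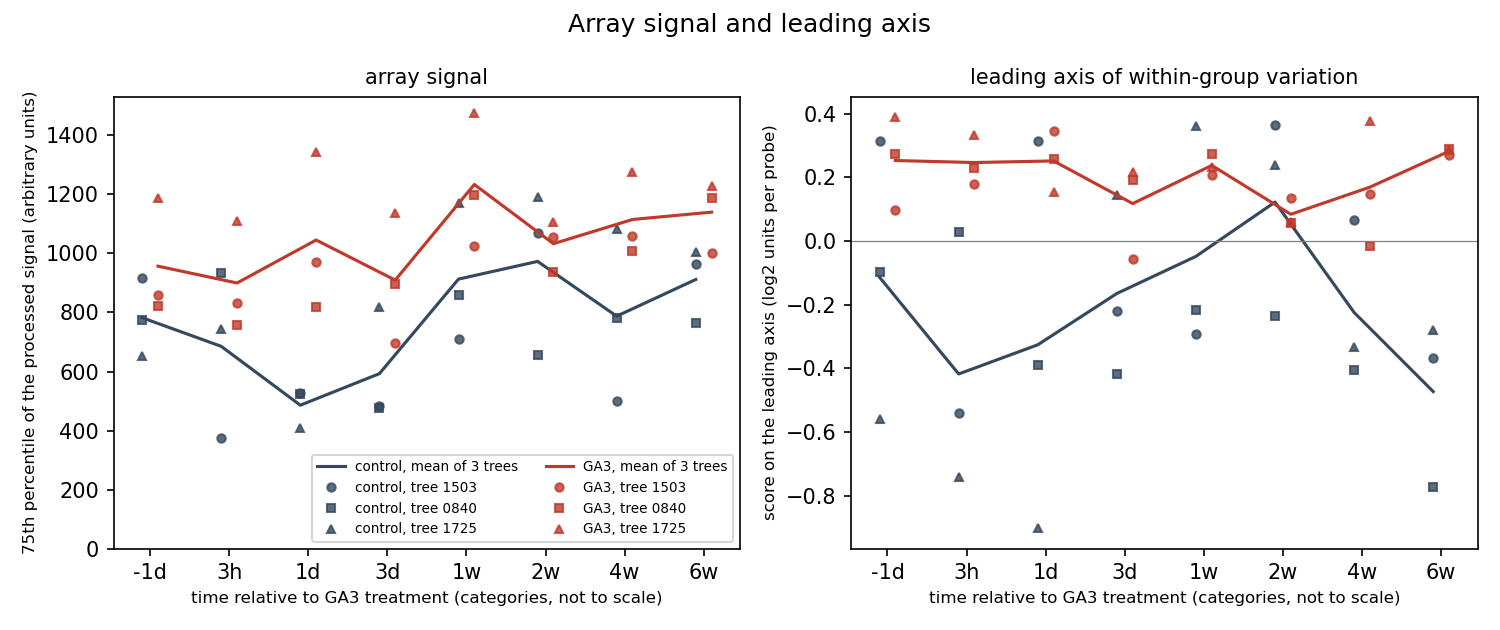
Array signal (left, 75th percentile of the processed intensity, arbitrary units) and score on the leading axis of variation within groups (right, log2 units per probe) for each array, with lines for the mean of 3 trees. The 24 GA3 arrays scored 0.21 ± 0.12 (SD) and the 24 control arrays -0.21 ± 0.37, and the 3 control arrays 1 day after treatment had signals between 408 and 526.

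The arrays from 1 day before treatment ask whether the individuals differed before GA3 was given. Isotigs coded --W- had a mean log2 fold change 0.21 below that of the other probes in the individuals to be treated (difference -0.21), and isotigs coded MSWR one 0.16 above it. Camera called both at a preset correlation (adjusted p = 0.0161 and 0.0212), and neither held with an estimated correlation (adjusted p = 0.755 for both). Fry, which tests a group against no change and not against other probes, gave adjusted p = 0.119 and 0.587. For single probes limma called 0 of 15327, with 1181 at an unadjusted p under 0.05, and 0 with tree as a block. The 6 arrays alone gave 2 calls, and leaving out tree 1725 gave 94. Trees differed at 8903 of the 15327 probes (moderated F test).

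At 3 hours the isotigs reCj20793 and reCj16013 were higher in GA3, by 5.99 (SE 0.83) and 5.35 (SE 0.73) on the log2 scale, with the same sign in 3 of 3 trees (adjusted p = 7.93e-05 for both, limma). Lower in GA3 were reCj20564, with a log2 fold change of -3.84 (SE 0.83, adjusted p = 0.0319), at least 11.2-fold since no GA3 array was above background, and reCj26851, with one of -2.85 (SE 0.65, adjusted p = 0.0486). Measured as a change since the day before treatment, reCj08835 rose by 5.24 (SE 0.97, adjusted p = 0.0366) and reCj31988 by 4.25 (SE 0.73, adjusted p = 0.0329) more in GA3 than in control. Neither isotig was above background on any array of the day before treatment, so these changes are fitted values and no bounds, and at 3 hours itself reCj31988 was at least 5.36-fold higher. Neither change was called without any 1 tree (adjusted p = 0.76, 0.0833 and 0.284 for reCj08835 and 0.76, 0.103 and 0.16 for reCj31988 without 0840, 1503 and 1725). The signal of reCj08835 at 3 hours was -1.53 ± 1.40 in GA3 and -5.77 ± 0.66 in control (SD, n = 3).

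The comparison at 3 hours asks for the earliest response after treatment, and limma called 33 probes, 24 higher and 9 lower, against 3 as a change since the day before treatment with slide as a block. With tree as a block it called 2008 (940 higher, 1068 lower). Without a block it called 8 when only probes above background on every array were tested. Leaving out the control array of tree 0840 gave 3077 calls, leaving out that of tree 1503 gave 12, and leaving out the GA3 array of tree 0840 or 1503 gave 10 or 13. Leaving out tree 0840, 1503 or 1725 throughout gave 0, 4 or 200, and leaving out arrays of low signal gave 13. With slide as a block, reCj20793 and reCj16013 had changes of 4.85 (SE 1.13) and 5.40 (SE 1.09) that were not called (adjusted p = 0.263 and 0.0883), and with the axis covariate both stayed called at 6.05 and 6.32 (adjusted p = 0.000178 and 1.88e-05). For reCj20564 and reCj26851 the slide block gave changes of -2.54 (SE 1.22) and -1.13 (SE 0.93), both with an adjusted p of 0.886, and the axis covariate gave -1.50 and -1.18 (adjusted p = 0.117 and 0.327).

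At 1 day reCj23242 was 5.81 higher in GA3 on the log2 scale (SE 0.89, adjusted p = 0.00144), at least 39.4-fold, as no control array was above background. Its signal was -0.16 ± 0.65 in GA3 and -5.97 ± 0.87 in control (SD, n = 3), and at 3 days -1.50 ± 0.69 in control against 0.49 ± 0.54 in GA3. It was the single probe called as a change since the day before treatment, by 7.02 (SE 1.22, adjusted p = 0.0405). This change was not called without tree 0840 or 1725 (adjusted p = 0.936 and 0.486). The isotig reCj29846 was higher by 6.59 (SE 1.90, adjusted p = 0.0453), and by 7.25 (SE 2.42, adjusted p = 0.843) as a change with slide as a block and 7.18 (adjusted p = 0.0554) with the axis covariate, so that the call was lost and the size was not. Lower in GA3 were reCj32918, with a log2 fold change of -3.65 (SE 0.93, adjusted p = 0.0326), and reCj26001, with one of -3.50 (SE 1.05, adjusted p = 0.0494). For reCj32918 the difference was -3.06 already on the day before treatment, its GA3 mean was -6.43 then and -6.36 at 1 day, and its change was -0.59 (adjusted p = 0.854). For reCj26001 the log2 fold change was -1.41 with the axis covariate (adjusted p = 0.348), and its change was -2.23 (adjusted p = 0.843). Without tree 0840 the rise of reCj23242 had an adjusted p of 0.262, and the rise of reCj29846 was not called without any 1 tree (adjusted p = 0.279, 0.0927 and 0.129 without 0840, 1503 and 1725).

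In all, limma called 701 probes at 1 day, 268 higher and 433 lower in GA3, of which 700 had the same sign in 3 of 3 trees and 469 changed by at least 1 on the log2 scale. Over all tested probes 54.4% had the same sign in 3 of 3 trees, and a call itself favours such agreement. Tree as a block gave 3089 calls, slide as a block through the change since the day before treatment gave 1, and the axis covariate beside tree gave 92, with 53 of the 701 still called and the balance of directions turned (68 higher and 24 lower). The control arrays at 1 day had the low signals given above and axis scores of -0.33 ± 0.61 (SD, n = 3), against 0.25 ± 0.10 in GA3. The count was 3450 without the control array of tree 1503, 4 without that of tree 1725, 18 without that of tree 0840, 2 without the GA3 array of tree 1503 and 3 without that of tree 0840. Leaving out tree 0840, 1503 or 1725 throughout gave 1, 2 or 243, and the 6 arrays alone gave 0. Without a filter 2202 probes were called and with normexp correction 3256.

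Few isotigs separated the groups between 3 days and 2 weeks. At 3 days reCj27090 was 2.99 higher in GA3 (SE 0.53, adjusted p = 0.0389), at least 4.13-fold. At 1 week reCj26580 was higher by 2.78 (SE 0.49, adjusted p = 0.0373) and reCj29193 by 2.57 (SE 0.49, adjusted p = 0.0451), and reCj22050 rose by 1.27 (SE 0.22, adjusted p = 0.0461) more than in control since the day before treatment. At 2 weeks reCj17268 was higher by 5.04 (SE 0.88, adjusted p = 0.00591) and reCj21566, with no control array above background, by at least 13.3-fold (fitted log2 fold change 4.84, SE 0.61, adjusted p = 4.68e-05). The isotig reCj32069 was lower at 2 weeks, at least 22.9-fold (fitted log2 fold change -6.33, SE 0.99, adjusted p = 0.0013), with a control signal of -2.11 ± 0.49 (SD, n = 3). The change since the day before treatment at 2 weeks was called for reCj17268, by 5.40 (SE 1.03, adjusted p = 0.0359), and for reCj19503, by a fitted 4.49 (SE 0.76, adjusted p = 0.0105). The isotig reCj19503 was above background on no array of the day before treatment, and at 2 weeks itself it was at least 11.9-fold higher in GA3. With slide as a block, the changes of reCj27090 (3.15, SE 0.75), reCj26580 (2.54, SE 0.71), reCj29193 (3.05, SE 0.60) and reCj32069 (-5.59, SE 1.24) were not called (adjusted p = 0.522, 0.9997, 0.139 and 0.196). The isotigs named for these 3 times had the same sign in 3 of 3 trees.

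The counts were 1 at 3 days (1442 at an unadjusted p under 0.05), 3 at 1 week (1677) and 7 at 2 weeks, 6 of them higher (335). With tree as a block they were 6, 13 and 14, and as a change since the day before treatment with slide as a block 0 (348 at an unadjusted p under 0.05), 1 and 5. At 3 days no call was left without the GA3 array of tree 1503 or 0840 or the control array of tree 1725 or 0840, and at 1 week none without any 1 of the 3 control arrays, while 5 were called without the GA3 array of tree 1503. At 2 weeks there were 2 calls without the GA3 array of tree 0840 and 4 without the control array of tree 1725. Leaving out tree 0840 throughout gave 0 at each of the 3 times, leaving out tree 1503 gave 0, 0 and 1, and leaving out tree 1725 gave 255, 127 and 91. The changes at 1 week were not called without any 1 tree (0 each), and at 2 weeks 0, 0 and 2 were called without tree 0840, 1503 and 1725.

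At 4 weeks reCj28306, coded M---, was higher in GA3 by 5.70 on the log2 scale (SE 0.73, adjusted p = 6.24e-05), with a signal of 0.44 ± 1.22 in GA3 and -5.26 ± 2.18 in control (SD, n = 3). It was also called as a change since the day before treatment, by 6.44 (SE 0.87, adjusted p = 0.000411), as was reCj19503 by a fitted 3.99 (SE 0.76, adjusted p = 0.0399). Before treatment neither was above background on any GA3 array. The signal of reCj28306 in GA3 had been -5.20 ± 0.56 at 1 week and -3.04 ± 1.15 at 2 weeks, and reached 2.42 ± 0.50 at 6 weeks. The isotig reCj33221 was higher by 5.73 (SE 1.14, adjusted p = 0.0285), while reCj28489 was lower by at least 17.2-fold (fitted log2 fold change -5.47, SE 1.13, adjusted p = 0.0285) and reCj24126 had a log2 fold change of -1.62 (SE 0.30, adjusted p = 0.019). As changes with slide as a block these 3 were of similar size, 6.17 (SE 1.68), -4.95 (SE 1.34) and -1.28 (SE 0.43), and were not called (adjusted p = 0.357, 0.356 and 0.738).

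Of the 17 probes called at 4 weeks, 13 were higher and 4 lower in GA3, against 1957 at an unadjusted p under 0.05 and 78 with tree as a block. The same 13 and 4 were called in the same direction at 6 weeks. As a change since the day before treatment with slide as a block, 5 were called, all higher. A single call was left without the GA3 array of tree 1503 or 1725, or without the control array of tree 1503 or 0840. Leaving out tree 0840, 1503 or 1725 throughout gave 0, 0 or 186 calls, and 0, 0 or 2 for the change. Leaving out arrays of low signal gave 1 and 3.

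At 6 weeks reCj30226 and reCj33073, both coded M---, had the largest log2 fold changes among the isotigs called higher in GA3 with the same sign in 3 of 3 trees. The signal of reCj30226 was 3.39 ± 0.19 in GA3 and -6.01 ± 3.43 in control (SD, n = 3), a log2 fold change of 9.40 (SE 1.62, adjusted p = 0.000186). That of reCj33073 was 2.95 ± 0.15 and -6.17 ± 3.19, a log2 fold change of 9.12 (SE 1.44, adjusted p = 6.9e-05). Both were above background in 1 of the 3 controls, that of tree 1725, where reCj30226 had -2.07. The isotig reCj33236 was lower by at least 169.5-fold (fitted log2 fold change -8.98, SE 2.76, adjusted p = 0.0161), and reCj30769 by at least 195.1-fold (fitted -8.79, SE 2.65, adjusted p = 0.0141). As changes since the day before treatment with slide as a block, these 2 were -2.39 (SE 3.94, adjusted p = 0.752) and -2.76 (SE 3.75, adjusted p = 0.695). By these estimates most of each difference was already present before GA3 was given, but their SEs are too large to settle the share. The axis covariate beside tree gave -1.07 and -1.97 (adjusted p = 0.75 and 0.575). Beside slide it gave changes of 1.685 and 0.756, in the opposite direction (adjusted p = 0.714 and 0.8997), so neither call held. Without tree 0840 or 1503 or the control array of tree 0840 the adjusted p values of both lay between 0.0863 and 0.264.

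**Figure D2:**
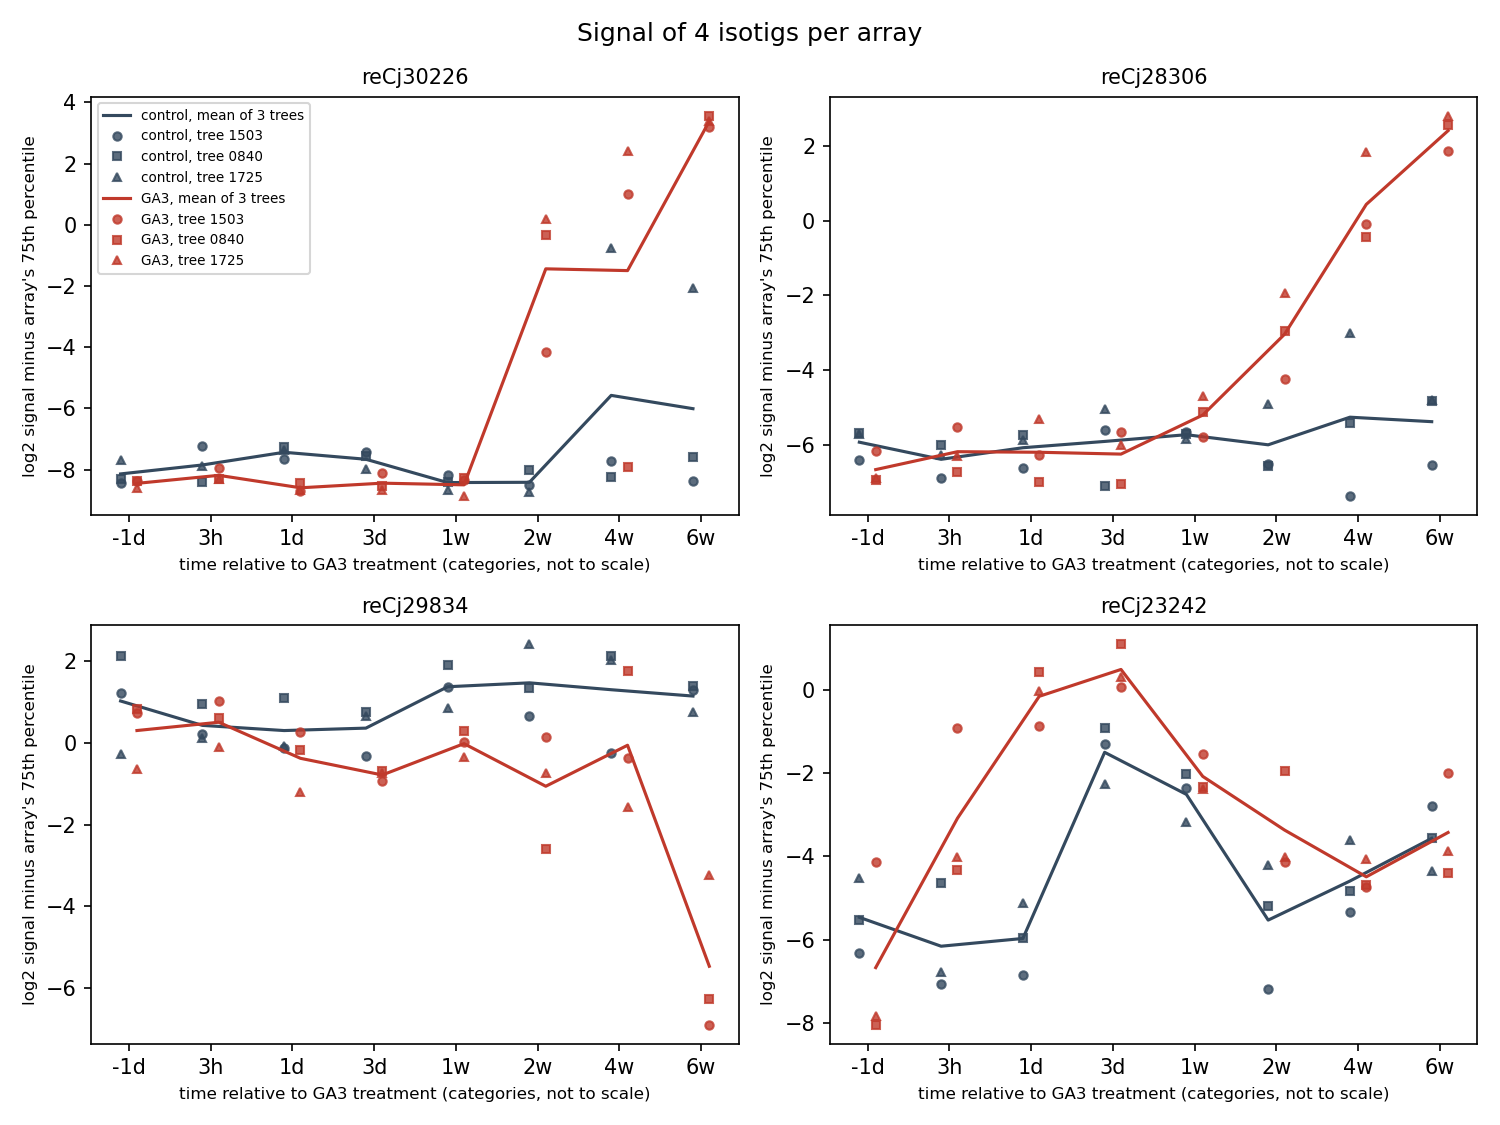
Signal of 4 isotigs on each array (log2, relative to the array's 75th percentile) by time, with symbols for the tree, colours for the treatment and lines for the mean of 3 trees. The isotig reCj30226 stood at 3.39 ± 0.19 (SD) in GA3 at 6 weeks, and reCj29834 fell to -5.47 ± 1.96.

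Measured as a change since the day before treatment, reCj30226 and reCj31827 (both M---) rose by 9.71 (SE 2.26, adjusted p = 0.00876) and 8.85 (SE 1.91, adjusted p = 0.00512) more in GA3 than in control, where that of reCj30226 is a fitted value and no bound, as it was above background on no array of the day before treatment. The isotigs reCj29834 and reCj29628, both coded -S--, fell by 5.89 (SE 1.1, adjusted p = 0.00156) and fell by 5.33 (SE 1.38, adjusted p = 0.0171) more. At 6 weeks reCj29834 had a signal of -5.47 ± 1.96 in GA3 and 1.15 ± 0.34 in control (SD, n = 3). The changes of reCj30226, reCj29834 and reCj29628 were not called without tree 0840 (adjusted p = 0.103, 0.086 and 0.0974), and those of all 4 isotigs were not called without tree 1503 (adjusted p = 0.287, 0.274, 0.176 and 0.374 in the order named).

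At 6 weeks, the last time sampled, limma called 3961 of 15327 probes, 2037 higher and 1924 lower in GA3, with the same sign in 3 of 3 trees for 3933 and a change of at least 1 on the log2 scale for 2637. Over all tested probes 66.9% had the same sign in 3 of 3 trees, and a call itself favours such agreement. With tree as a block 5925 were called. The change since the day before treatment with slide as a block gave 1090, of which 620 rose and 470 fell, and 852 of the 1090 were among the 3961. Without the slide block the change gave 250, of which 175 rose and 75 fell. The axis covariate beside tree left 2197 (1048 higher and 1149 lower), of which 1413 were among the 3961, and the axis scores were 0.28 ± 0.01 in GA3 and -0.47 ± 0.26 in control (SD, n = 3). The count was 2595 without the GA3 array of tree 0840, 2358 without the control array of tree 0840, and 388 or 1921 without tree 0840 or 1503 throughout. For the change it was 44 without tree 0840, 44 without tree 1503 and 2235 without tree 1725.

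**Figure D3:**
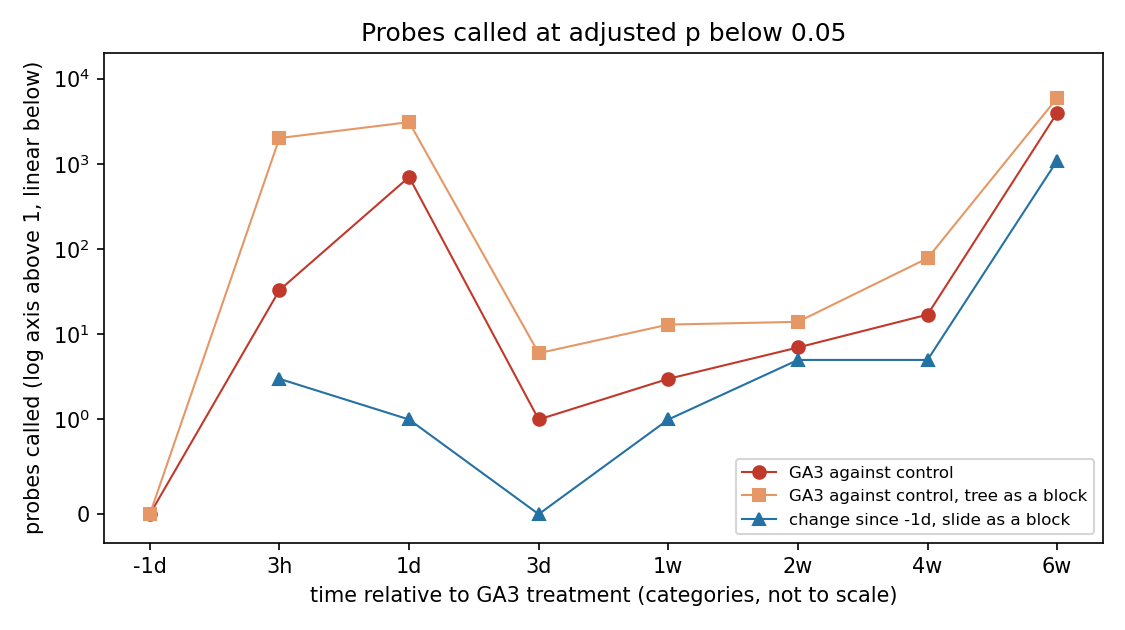
Number of probes called at an adjusted p under 0.05 at each time (logarithmic axis above 1), for GA3 against control without a block, with tree as a block, and for the change since the day before treatment with slide as a block. Without a block the count was 701 at 1 day, 1 at 3 days and 3961 at 6 weeks.

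The isotig names group the 6-week response further. Among the 140 tested isotigs coded M---, 46 were higher and 17 lower in GA3, and the mean log2 fold change was 1.03 above that of the other probes, while the median log2 fold change was 0.44 and with the axis covariate 0.16. As a change since the day before treatment 33 of them (23.6%) rose, against 3.9% of the other probes (Fisher's exact odds ratio 7.67, adjusted p = 4.29e-15). Their mean signal relative to the day before treatment was 0.86 ± 0.16 in GA3 and -0.15 ± 0.39 in control (SD, n = 3). The control of tree 1725 stood apart at 0.293, against -0.402 and -0.342 in the controls of trees 1503 and 0840. Of the 1588 isotigs coded -S--, 395 (24.9%) were lower, against 11.1% of the others (Fisher's exact odds ratio 2.64, adjusted p = 3.72e-44), and their mean signal was -0.38 ± 0.01 in GA3 and 0.01 ± 0.06 in control. Fisher's test treats isotigs as independent, and camera with an estimated correlation called neither of these groups.

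Camera at a preset correlation called both M--- and -S-- at 6 weeks (adjusted p = 0.00244 for each), and so did camera with tree as a block (0.0105 and 0.00279) and on the change with slide as a block (0.00136 and 0.00281). Neither held with an estimated correlation (adjusted p = 0.755 for each). Against no change, fry gave adjusted p = 0.00183 and 0.00501. The preset camera also called -S-- lower at 1 week (mean difference from the other probes -0.28, adjusted p = 9.38e-05) and at 4 weeks (-0.21, adjusted p = 0.0111), and MSWR higher at 1 week (0.18, adjusted p = 0.00244), which gave adjusted p = 0.482, 0.755 and 0.755 with an estimated correlation. The MSWR call at 1 week had an adjusted p of 0.397 with slide as a block. Isotigs are not independent replicates in Fisher's test. Among probes above background on every array, 15 of 72 M--- isotigs were higher at 6 weeks against 13.0% of the others (Fisher's exact odds ratio 1.76, p = 0.0542), and 9 of 72 rose as a change (odds ratio 3.85, p = 0.00114).

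**Figure D4:**
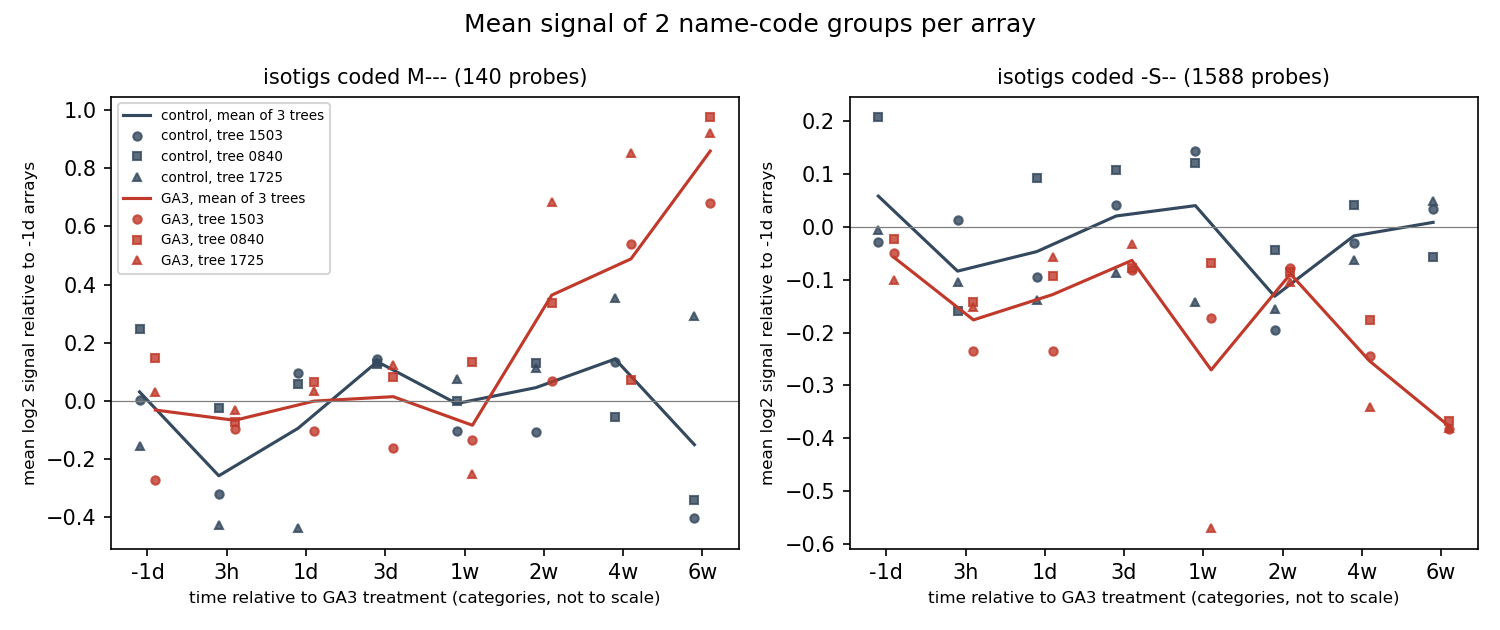
Mean log2 signal per array of the isotigs coded M--- (140 probes) and -S-- (1588 probes), relative to the mean of the arrays from the day before treatment, with symbols for the tree and lines for the mean of 3 trees. At 6 weeks the M--- mean was 0.86 ± 0.16 (SD) in GA3 and -0.15 ± 0.39 in control.

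With the arrays of a slide taken as independent, a moderated F test called 4421 probes between GA3 and control at some time after treatment. Of these, 2661 were first called in the comparisons at single times at 1 week or later, 710 at 3 hours, 1 day or 3 days, and 1050 at no single time. Among all probes called at a single time, 3479 were first called at 1 week or later, 3459 of these at 6 weeks, and 715 were first called at 3 hours, 1 day or 3 days. This timing depends on the block, since with tree as a block 3863 probes were first called at 3 hours, 1 day or 3 days and 3416 later. None of the 715 stayed called at every later time, and 480 of them were called again in the same direction at 6 weeks. Since only 1, 3 and 7 probes were called at 3 days, 1 week and 2 weeks, staying called was hardly possible. The loss of the calls therefore does not show that an early difference passed. The 12 probes first called at 4 weeks were all called in the same direction at 6 weeks. With tree as a block the F test called 7144, and as a change since the day before treatment with slide as a block 227. Arrays of a slide are repeated samples of 1 individual, with a consensus correlation of 0.335 within slides. With slide as a random block the count was several times lower than 4421, as given with the alternatives below. Without a block the F test called 76 without tree 0840, 713 without tree 1503 and 3666 without tree 1725.

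In GA3, reCj30226 rose from the day before treatment to 6 weeks by 11.84 (SE 1.62, adjusted p = 1.03e-05), at least 979.6-fold, and reCj33073 by 10.58 (SE 1.44, adjusted p = 1e-05), at least 724.2-fold. The largest falls in GA3 were those of reCj31416, which fell by 7.59 (SE 1.43, adjusted p = 0.000648), and reCj19317, which fell by 6.58 (SE 2.09, adjusted p = 0.0451), at least 27.5-fold. In control reCj31416 had a log2 fold change of -6.52 (SE 1.43, adjusted p = 0.00842), and reCj19317, with no array above background at 6 weeks, was lower by at least 24.7-fold (fitted -5.71, SE 2.09), which passed the F test over time (adjusted p = 0.0339) and missed the threshold for the single contrast (adjusted p = 0.12). The largest rises in control were 4.78 (SE 0.73, adjusted p = 0.000171) for reCj30868, at least 8.34-fold, and 4.67 (SE 0.90, adjusted p = 0.00274) for reCj31824, at least 8.17-fold.

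The F test over time called 523 probes in control and 827 in GA3, and with tree as a block 1998 and 2322. With slide as a block it called 2441 and 2833, of which 1230 were called in both treatments, against 451.2 if the calls were independent. At 6 weeks against the day before treatment, 551 probes differed in control (250 higher) and 1179 in GA3 (645 higher). Leaving out tree 0840 or 1503 gave 10 or 16 probes over time in control and 79 or 210 in GA3, and leaving out tree 1725 gave 447 in GA3. The date of sampling and the place on the slide change with time in both treatments.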

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

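The tests of the leading axis, of an offset between slides, of scan month and of the origin of the control RNA were chosen only after the results had been seen. The splits of the samples and the test for mixed RNA were planned, but the repeat of the latter over fewer isotigs was not.

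The GA3 effect differed between the day before treatment and 3 hours for 3 probes, by a test of the difference itself with slide as a block. It differed between 4 and 6 weeks for 1 probe by the same test. Between each of the other neighbouring times, from 3 hours to 4 weeks, 0 probes were called, so a fall of the effect after 1 day was not found. Spike-in spots, which the comparisons do not use, had a median intensity of 2420 on the GA3 slide of tree 0840 and of 1380 on that of tree 1725, above the highest control array (1164). The GA3 slide of tree 1503 had 695.6, within the range of the control slides (682.4 to 940.5), so not all GA3 slides were higher.

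The 701 calls at 1 day, a time when all 3 control arrays had a low signal, had a median log2 fold change of 1.19 in their own direction. With tree as a block and the axis as a covariate, 53 of them stayed called, all in the same direction, and the median was 0.66, so variation between arrays along this axis may account for many of the calls. An offset between slides stays open, as the same probes already differed by a median of 0.5 in the same direction before treatment, and the change since then had a median of 0.67 with 1 probe still called. A response to GA3 on the first day is untested apart from these, because each slide holds 1 treatment and no control array at 1 day had a higher signal.

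The 3961 calls at 6 weeks had a median log2 fold change of 1.29 in their own direction. A constant offset between slides does not account for all of the calls, since 852 stayed called as a change since the day before treatment. The same probes differed by a median of 0.29 before treatment, 81.9% of them in the same direction, and the change had a median of 0.97. As the probes were picked by their difference at 6 weeks, these medians cannot give the share of such an offset. A constant offset by scan month, as modelled, did not remove most of the calls, as 3497 stayed called with tree and scan month as blocks. This does not exclude scan month, because the slides of the earlier month all held GA3 arrays. Beside tree, month is set apart only by the GA3 slide of tree 1725 and cannot be told from that individual. The axis stays open for part of the 3961 calls, because with it as a covariate the median fell to 0.599 and 1413 stayed called. However, the axis itself differs between the groups at 6 weeks. The GA3 treatment, which the design names, is among the open explanations, and differences between the treated and untreated individuals that appeared after the first sampling were not tested.

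In the control of tree 1725 at 6 weeks, 7 isotigs that are bright on the GA3 array of this tree and below background in the other 2 controls were present. The array does not appear to hold RNA of another tree, since its deviations correlated at 0.531 with the GA3 array of the same tree. Those with the GA3 arrays of other trees, at most -0.25, are no separate evidence, as the deviations of a group cancel over its trees. For mixing with RNA of that GA3 array, the control minus GA3 difference had an SD of 2.17 over the 7 isotigs. This was above the limit of 1, which by the rule set in advance counted against mixing. After this result was seen, the test was repeated without 3 of the 7, which were already above background in this control before treatment. Over the other 4 the SD was 0.09 around a median of -5.51, which is 2.2% of the GA3 level, and at 4 weeks, on a separate array, 3 isotigs gave 11.3% with an SD of 0.38. Mixed RNA and a small share of strobilus tissue in this control cannot be told apart, as both could give a constant ratio.

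Other splits of the samples into groups of equal size were counted for each result. The 6 arrays of 1 time make 10 splits, too few for a share under 0.05. The real count and the highest other count were 0 and 1 on the day before treatment (10 of 10 splits gave as many), 33 and 2 at 3 hours, 701 and 1 at 1 day, 1 and 0 at 3 days, 3 and 1 at 1 week, 7 and 1 at 2 weeks, 17 and 6 at 4 weeks, and 3961 and 1 at 6 weeks, where 1 split, the real one, gave as many at each time after treatment. The real split parts all 3 trees, and the 3 other splits that do so gave at most 1, on the day before treatment and at 1 week, and 0 elsewhere; the remaining 6 splits part 1 tree.

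For the change since the day before treatment, the 6 slides also make 10 splits, too few for a share under 0.05. The real and the highest other count were 3 and 4 at 3 hours (2 splits as large), 1 and 0 at 1 day, 0 and 0 at 3 days (10 of 10), 1 and 0 at 1 week, 5 and 80 at 2 weeks (2 splits as large), 5 and 0 at 4 weeks, and 1090 and 1 at 6 weeks. The split with 80 calls at 2 weeks and 4 at 3 hours sets the GA3 slides of trees 1503 and 1725 with the control slide of tree 1725, and 80 is several times the real count, which points to a structure of the samples. For any time after treatment the real count was 4421 and the highest other 1015. That count came from a split that sets the GA3 slides of trees 1503 and 0840, both scanned in the earlier month, with the control slide of tree 1503. The same 2 GA3 slides with the control slide of tree 1725 gave 0. All splits that part 1 tree gave between 404 and 1015, so these counts went with the parting of trees and not with scan month. With tree and scan month as blocks 2200 probes were called. The other splits that part all 3 trees gave 0 in each of these comparisons.

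For the courses over time, 100 regroupings of the 24 arrays of a treatment were counted, the real one included. In control 12 of 100 gave as many probes as the real 523, with a highest of 3942, so chance is not excluded there, and the count several times the real one points to a structure of the samples; of 50 separate regroupings that kept the arrays within their trees, the real one included, 3 gave as many, with a highest of 1652. In GA3 1 of 100, the real one, gave as many as 827, with a highest other of 291. Within trees it was 1 of 50, with a highest other of 67. A count this high was thus rare under regrouping, but time and place on the slide are confounded, so it is not tied to time alone. For the trees, 1 of 15 ways to pair the slides gave as many probes as the real 8903, with a highest other of 6982, and 15 are too few for a share under 0.05.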

How the results depend on the processing

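The settings with scan month, the leading axis or arrays of low signal were chosen after seeing the data, as were the alternatives for code groups; the others were planned. Under the alternatives run, 362 values of named isotigs stayed called, 231 were no longer called and 0 turned direction, while 156 counts stayed within 1.5 times the reported one and 159 did not. This tally leaves out slide with the axis for isotigs named by GA3 against control. There reCj33236 and reCj30769 at 6 weeks turned direction, to 1.685 and 0.756. The causes were not tested except where fewer probes or arrays explain a lower count. With quantile normalisation 2 probes were called at 3 days, and for the change since the day before treatment 1 at 3 hours, 0 at 1 day, 1 at 2 weeks and 2 at 4 weeks. With normexp correction 13, 3256, 2 and 0 were called at 3 hours, 1 day, 3 days and 1 week, and 0, 0, 1 and 2 for the change at 3 hours, 1 day, 2 weeks and 4 weeks. Without a filter 2202, 0 and 1 were called at 1 day, 3 days and 1 week, and 0 for the change at 1 week. Among probes above background on every array (fewer tested) 8, 0, 0, 0 and 7 were called at 3 hours, 3 days, 1 week, 2 weeks and 4 weeks, and 0, 0, 1 and 1 for the change at 3 hours, 1 day, 2 weeks and 4 weeks. With outlier spots kept 2 were called at 3 days and 0 for the change at 1 week, with a trended and robust variance 0 at 3 days, and with a log2 fold change of at least 1 2637 at 6 weeks.

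With tree as a block 2008, 3089, 6, 13, 14 and 78 were called at 3 hours, 1 day, 3 days, 1 week, 2 weeks and 4 weeks, 7144 at any time, 1998 over time in control and 2322 in GA3, and 3863 were first called at 3 hours, 1 day or 3 days (a setting added after seeing the data). With slide as a random block 18, 139, 0, 0 and 4 were called at 3 hours, 1 day, 3 days, 1 week and 4 weeks, 537 at any time, 2131 over time in control and 2376 in GA3. With slide as a fixed block 3, 1, 0, 1, 5 and 1090 were called at 3 hours, 1 day, 3 days, 1 week, 4 weeks and 6 weeks through the change, and 2441 and 2833 over time in control and GA3. Without the slide block the change gave 0, 0, 1 and 250 at 1, 2, 4 and 6 weeks. The 6 arrays of a time alone gave 2 before treatment and 0, 0, 0, 0, 1 and 0 from 3 hours to 4 weeks. Tree and scan month as blocks gave 1930, 0, 0 and 5 at 1 day, 3 days, 1 week and 4 weeks and 2200 at any time. Tree with the axis gave 92, 33, 33, 22, 48 and 2197 from 1 day to 6 weeks and 2050 at any time; slide with the axis gave 11, 2, 18 and 1636 for the change at 3 hours, 1 day, 4 weeks and 6 weeks. Without arrays of low signal 13, 1 and 1 were called at 3 hours, 1 week and 4 weeks, and 0, 0, 3 and 3 for the change at 3 hours, 1, 2 and 4 weeks; at 1 day no control array is left, so this was not run.

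Leaving out 1 tree or array gave 0 to 94 calls before treatment, 0 to 3077 at 3 hours, 1 to 3450 at 1 day, 0 to 255 at 3 days, 0 to 127 at 1 week, 0 to 91 at 2 weeks, 0 to 186 at 4 weeks, 388 to 3859 at 6 weeks, 76 to 3666 at any time, 10 to 523 over time in control and 79 to 447 in GA3. For the change it gave 0 to 2 at 3 hours, 0 to 1 at 1 day, 0 at 3 days and 1 week, 0 to 2 at 2 weeks and at 4 weeks, and 44 to 2235 at 6 weeks. Of the results for code groups, 37 were no longer called, those with an estimated correlation among them, and 20 stayed called. The share of higher probes at 1 day was 38.2%, against 14.8% with normexp correction. Alternatives on gene lists could not be run without gene names, and the deposited value table, whose values are identical, gave the same counts; being void as a test, it is left out of the totals above. Signal over background limits the fold changes of dim isotigs.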

Other observations

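The test on the letter M was chosen only after the GA3 effect on these isotigs had been seen, and the other tests on code groups after the names were read.

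Calls at 6 weeks were spread unevenly over other code groups as well, although camera without a block called none of those named here, at the preset correlation (adjusted p = 0.306 for -S-R, 0.207 for M--R and 0.723 for ----) or an estimated one (adjusted p = 0.755, 0.847 and 0.937). On the change with slide as a block, camera at the preset correlation called -S-R (adjusted p = 0.0116) and M--R (adjusted p = 0.0242) but not ---- (adjusted p = 0.165), and with an estimated correlation none of them (adjusted p = 0.255, 0.745 and 0.871). Isotigs coded -S-R were more often lower in GA3, 133 of 620 (21.5%) against 12.2% of the other probes (Fisher's exact adjusted p = 6.81e-09), and 43 of them fell as a change since the day before treatment. Isotigs coded M--R were more often higher, 10 of 29 (34.5%) against 13.3% (Fisher's exact adjusted p = 0.015). Isotigs coded ---- were less often lower, 226 of 2520 (9.0%) against 13.3% (Fisher's exact adjusted p = 1.85e-08).

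On the GA3 arrays of tree 0840, reCj30226 had a signal of -0.34 at 2 weeks, -7.92 at 4 weeks, where it was not above background, and 3.57 at 6 weeks. In the other 2 trees under GA3 it had -4.16 and 0.18 at 2 weeks, 1.02 and 2.41 at 4 weeks, and 3.20 and 3.39 at 6 weeks, in the order 1503 and 1725. In control, tree 1725 had -0.75 at 4 weeks and -2.07 at 6 weeks, and the other 2 trees lay between -8.36 and -7.59 at both times.

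Of the 268 probes higher at 1 day, 135 were higher at 6 weeks, and of the 433 lower ones 341 were lower. Both times share the same slides and individuals, and the log2 fold changes of the day before treatment correlated across probes with those at 1 day (Pearson r = 0.664) and at 6 weeks (r = 0.5), so the overlap is not set against chance; probes are not independent replicates. The 6 probes higher at 2 weeks were all higher at 6 weeks, and so were the 13 of 4 weeks.

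What the letter M stands for is not given in the files. From the day before treatment to 6 weeks, 39 of 140 isotigs coded M--- rose in GA3, against 1542 of 15187 other probes (Fisher's exact odds ratio 3.42, p = 4.47e-09), and in control 6 of 140 against 883 of 15187 (odds ratio 0.725, p = 0.585). These counts restate the larger rise in GA3 than in control that prompted them, so they do not test whether M marks isotigs of reproductive origin, which stays open. The odds ratio for being higher in GA3 at 6 weeks was 5.23 with tree as a block and the axis as a covariate. Isotigs are not independent replicates, and the group was not called by camera with an estimated correlation (adjusted p = 0.755).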
